A study of Mus musculus with 12 samples.

How the data were processed

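RNA-seq values were deposited for 12 mouse libraries of type 1 conventional dendritic cells (cDC1) from inguinal lymph nodes, 3 in each of 4 groups set by tumor (subcutaneous KPC tumor or none) and by CD40 agonist (given or not). Per the labels' protocols, total RNA was extracted with Qiagen RNeasy Plus Micro kits and libraries were made with the NEBNext Ultra II Directional kit. Per the submitters' processing notes, transcripts were quantified with Salmon against the mm10 build, with no version or annotation release given, while the name of the deposited tables speaks of sailfish, an earlier program of this kind. The labels give no dose, no time of treatment or of sampling and no sort gates. They do not say whether the libraries of a group come from separate animals, so the p-values measure only the spread between these samples.

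The authors deposited expected counts per transcript, which are estimated read counts without normalization, and TPM per transcript, also deposited, which are scaled by transcript length and to the same total in every library. Both tables hold 136288 Ensembl transcripts and 1 column per library. With the GENCODE M21 annotation of GRCm38, 136176 transcripts were assigned to 53458 genes; the other 112 held between 0.0279% and 0.0457% of the counts of a library and were left out. Values were summed per gene and the expected counts rounded to whole numbers, and 31027 genes had a count in at least 1 library. Gene identifiers that share a symbol with another (110 identifiers beyond the first of each symbol) were kept apart. Expected counts summed to between 22855143 and 27163393 per library. Correlations of log2 CPM ran from 0.907 to 0.949 within groups and from 0.899 to 0.949 between groups, and the common biological coefficient of variation was 58.4%.

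Groups were compared in R 4.3.3 with edgeR 4.0.16: trimmed mean of M values (TMM) normalization with factors from 0.936 to 1.074, filterByExpr by group (minimum count 10, minimum total 15), which left 18095 genes, a model with the 4 groups over all 12 libraries (8 residual degrees of freedom), quasi-likelihood F tests (two-sided) and Benjamini-Hochberg adjustment with a threshold of 0.05 on the adjusted p. The 4 pairwise comparisons were the CD40 agonist without and with tumor and the tumor without and with CD40 agonist, and the remaining contrast was their interaction. The groups, the comparisons, the tests, the gene lists, the rule for named genes and most of the alternatives were set before the data were examined. The dispersion setting of glmQLFit (legacy) was not named in that plan other than as an alternative with legacy = TRUE, so legacy = FALSE was used. In this version legacy = TRUE is the default, and its counts were seen first. With legacy = FALSE the 5 counts of genes past the threshold were 261, 124, 0, 36 and 0, and with legacy = TRUE they were 198, 61, 0, 0 and 0, in the order of the comparisons above.

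The plan fixed 23 lists of genes (dendritic cell functions, signaling, stress, metabolism, cell cycle) and 15 lists of markers of other cells or of sex, 38 in all. Each was tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 38 lists, and again with camera and an estimated correlation and with fry, which tests whether the genes of a list move on balance in 1 direction. Members past the threshold are counted over all genes and adjusted over the list alone. Genes named as results are a fixed panel of 14, then up to 10 per direction with the largest log2 fold change among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries (made up to 5 per direction by lowest p, as values only), and up to 4 members past the threshold per list; any other gene named was chosen after its values were seen, which holds for the shared genes of the CD40 comparisons and for the single libraries' values.

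The tests were tried on simulated data made from these libraries with 200 genes changed by known folds. edgeR with legacy = FALSE recovered 14% of the genes changed 2-fold and 72% of those changed 4-fold in the CD40 comparison without tumor, and 12% and 66% in that with tumor. False calls made up 6.4%, 8.5%, 13.5%, 3.4% and 9.1% of its calls in the 5 comparisons, over the nominal 5% in 4 of them, against 4.4%, 3.6%, 4.7%, 2.3% and 3.3% with legacy = TRUE and 29%, 26.1%, 30.3%, 23.1% and 32.1% with DESeq2. No called gene had the wrong direction with edgeR. A list raised 1.5-fold was found by camera with the preset correlation (adjusted p = 7.1e-23), with an estimated correlation (0.000597) and by fry (0.00129), with 0 of the other 37 lists past the threshold. The simulated genes were drawn independently of each other. In the real libraries genes of a list move together, with an estimated correlation of 0.819 for the mature dendritic cell list without tumor. The simulation therefore cannot show how often lists pass falsely here, and its shares of false calls do not cover genes that move together. Its changed genes were drawn only above a minimum mean expression, so the recovery does not describe the least expressed genes.

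The alternatives set in advance were size factors of the DESeq2 type (RLE), DESeq2 1.42.0, no filter on low counts, a mean of at least 5 CPM, a fit of only the 6 libraries compared, limma-trend on log2(TPM + 1) with and without the filter and on log2(TPM + 0.1), limma-voom with sample quality weights, edgeR with legacy = TRUE, each library left out in turn, and the title prefix as a block. The prefixes are 091218 and 091318, each with 1 library of every group, 091418 with library 3 of every group but NoTumor-NoCD40, and 092518 with library 3 of NoTumor-NoCD40 alone. A term for prefix 092518 fits its only library exactly, so a fit with the prefix in effect leaves NoTumor-NoCD40 library 3 out. No label says what the prefix stands for. For that reason the plan left it out of the main model, and the libraries were not treated as paired. Residuals of libraries that share a prefix correlated at a median of 0.063 over 15 pairs (0.004 to 0.228) and those of the other 39 pairs at -0.029. These correlations are weak but all positive for a shared prefix, so they do not exclude an effect of the prefix. Alternatives added after seeing the data were the 8 libraries of prefixes 091218 and 091318 with the prefix as a block, the mean expression of the mature dendritic cell list or of the B cell list as a covariate, and the counts outside immunoglobulin genes and the listed B and plasma cell markers. No deposited sample or column was left out.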

Results

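RNA was sequenced from type 1 conventional dendritic cells (cDC1, the dendritic cells that take up cell debris and present it to CD8 T cells) taken from mouse inguinal lymph nodes. The 12 libraries fall into 4 groups of 3 by the presence of a subcutaneous KPC tumor (KPC is the usual name of cells from a mouse model of pancreatic cancer) and by treatment with an agonist of CD40, the receptor through which helper T cells activate dendritic cells. The groups are named NoTumor-NoCD40, NoTumor-CD40, Tumor-NoCD40 and Tumor-CD40, after the labels, with libraries 1 to 3 in each. The deposited expected counts summed to between 22855143 and 27163393 per library, and 20167 to 22523 genes had a count in each library. Expression of single genes is given in normalized CPM (counts scaled to a common library total), as mean ± SD of the 3 libraries of a group. Fold changes are on the log2 scale with a standard error (SE). For single genes it was derived from the test, as the absolute log2 fold change over the square root of the F statistic. Genes are placed on the mouse genome build GRCm38, which is mm10.

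The comparison of NoTumor-CD40 with NoTumor-NoCD40 libraries asked what the agonist changed in cDC1 without a tumor. Interferon-stimulated genes, several ligands that restrain or stimulate T cells and some genes of the maturation program rose. Oas3 (ENSMUSG00000032661, chromosome 5, 120753098 to 120777661), an oligoadenylate synthetase of the antiviral response, rose from 13.6 ± 2.93 to 101 ± 16.1 CPM (n = 3 per group), a log2 fold change of 2.89 ± 0.23 (SE). Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), which encodes the checkpoint ligand PD-L1, rose from 38.8 ± 15.3 to 253 ± 102 CPM, a log2 fold change of 2.71 ± 0.35 (SE). Ccr7, the chemokine receptor that guides mature dendritic cells to lymph nodes, rose from 604 ± 225 to 2220 ± 953 CPM, and Cd80, a ligand of the T cell receptors CD28 and CTLA-4, rose from 29 ± 4.41 to 97.9 ± 35.3 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 8.24e-05 for Oas3, 0.00335 for Cd274, 0.0326 for Ccr7 and 0.00717 for Cd80. In all, 261 of the 18095 genes tested passed the adjusted threshold of 0.05, of which 246 were higher and 15 lower with the agonist.

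Of the 40 measured genes of the type I interferon response list, 14 rose without a tumor and none fell, and 27 rose when adjusted over the list alone. The median log2 fold change of the list was 1.02, and Oasl2 (3.09 ± 0.33 SE), Oasl1 (2.87 ± 0.32) and the antiviral enzyme Rsad2 (2.35 ± 0.33) were among the larger changes. Reads of Oas and Oasl genes can be shared between close family members, so the division among them is less certain than their sum. Of 30 interferon gamma response genes, 6 rose and 17 rose when adjusted over the list alone, with a median of 0.83. They included Gbp5, a guanylate-binding protein (1.71 ± 0.37), and the transcription factor Irf1 (1.59 ± 0.37), as well as Cd274 and Icam1, which other lists here also hold. Of 18 coinhibitory genes, 5 rose, and 8 rose when adjusted over the list alone, with a median of 1.13. Besides Cd274 these included Pdcd1lg2, which encodes PD-L2 (1.71 ± 0.32), Nectin2 (3.09 ± 0.41) and Cd200 (1.92 ± 0.36). By camera with a preset correlation of 0.01 the adjusted p was 1.19e-31 for the type I interferon list, 8.6e-15 for the interferon gamma list and 1.31e-08 for the coinhibitory list. These 3 lists also passed with an estimated correlation, at adjusted p = 0.0272, 0.0318 and 0.00915.

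Of 15 costimulatory genes, 5 rose without a tumor and 9 rose when adjusted over the list alone, with a median log2 fold change of 1.04. The tumor necrosis factor family ligands Cd70 (3.01 ± 0.47 SE) and Tnfsf9 (2.30 ± 0.35) were among them, while Cd86 had a value of 0.35 ± 0.26 and Cd40 itself 1.04 ± 0.29, neither past the threshold (edgeR adjusted p = 0.507 and 0.0983). Of 32 genes of the mature or migratory dendritic cell program, 5 rose and 20 rose when adjusted over the list alone, with a median of 1.04. The chemokine Ccl17 (2.33 ± 0.50), Bcl2l14 (2.54 ± 0.31) and Traf1, a signaling adaptor (1.45 ± 0.29), were examples. Of 31 NF-kB and CD40 signaling genes, 4 rose and 18 rose when adjusted over the list alone, with a median of 0.91, Bcl3 (1.20 ± 0.19) and Nfkbie (0.95 ± 0.21) among them. Of 24 measured cytokines and chemokines, 4 rose and 8 rose when adjusted over the list alone, with a median of 0.86. The interleukin 27 subunits Il27 (2.94 ± 0.49) and Ebi3 (2.09 ± 0.38) both rose, and so did Il1rn, the interleukin 1 receptor antagonist (3.10 ± 0.66), whereas Il12b was at 1.12 ± 0.28 (edgeR adjusted p = 0.0618). The camera adjusted p with the preset correlation was 1.11e-08, 9.47e-18, 2.84e-14 and 4.81e-05 for these 4 lists in turn. None of the 4 passed with an estimated correlation, at adjusted p = 0.0825, 0.346, 0.255 and 0.207.

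The genes with the greatest positive changes without a tumor included Upp1, a uridine phosphorylase (4.09 ± 0.55 SE), Vdr, the vitamin D receptor (3.73 ± 0.47), Cdk5r1 (3.62 ± 0.44) and Abca13, a lipid transporter (4.15 ± 0.59). Among the 15 lower genes were the mitochondrial ribosomal protein genes Mrpl41 (-1.14 ± 0.26) and Mrpl12 (-0.78 ± 0.18), and Dtymk, the thymidylate kinase of nucleotide synthesis (-1.01 ± 0.20). Of 30 cDC1 identity genes only Ly75, the uptake receptor DEC-205, passed, and it rose (1.12 ± 0.24). The chemokine receptor Xcr1 averaged 659 ± 134 CPM without and 277 ± 243 CPM with the agonist, and did not pass (edgeR adjusted p = 0.356). The identity list had a median of -0.75, at a camera adjusted p of 0.000367 with the preset correlation and an adjusted p = 0.549 with an estimated correlation. Markers of other cells moved as well: Spib of the plasmacytoid dendritic cell list (2.56 ± 0.42), Esam of the cDC2 list (1.49 ± 0.33), Ly6c2 of the monocyte list (1.63 ± 0.29) and Kdr of the endothelial list (2.50 ± 0.57) rose. Of 9 monocyte markers 3 were higher and 3 lower when adjusted over the list alone, and the summed expression of the list, 10 genes with 1 below the filter, averaged 757 ± 96 CPM without and 356 ± 171 CPM with the agonist. The B cell list had a median of 1.16 with 0 of 16 members past edgeR's threshold and 2 higher when adjusted over the list alone (camera adjusted p = 0.000537 with the preset correlation and 0.425 with an estimated correlation). Each library weighed on the count, which was 128, 23 and 22 without NoTumor-NoCD40 library 1, 2 and 3, and 80, 946 and 48 without NoTumor-CD40 library 1, 2 and 3. The sample titles carry a date-like prefix with at most 1 library per group in each, so no prefix gives a value of its own. With the prefix as a term in the model, 48 genes passed, of which 42 were among the 261. No other library has the prefix of NoTumor-NoCD40 library 3, so the term fits that library exactly and in effect leaves it out. Leaving it out without the term gave 22, so the fall to 48 cannot be read as an effect of the prefix.

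**Figure D1:**
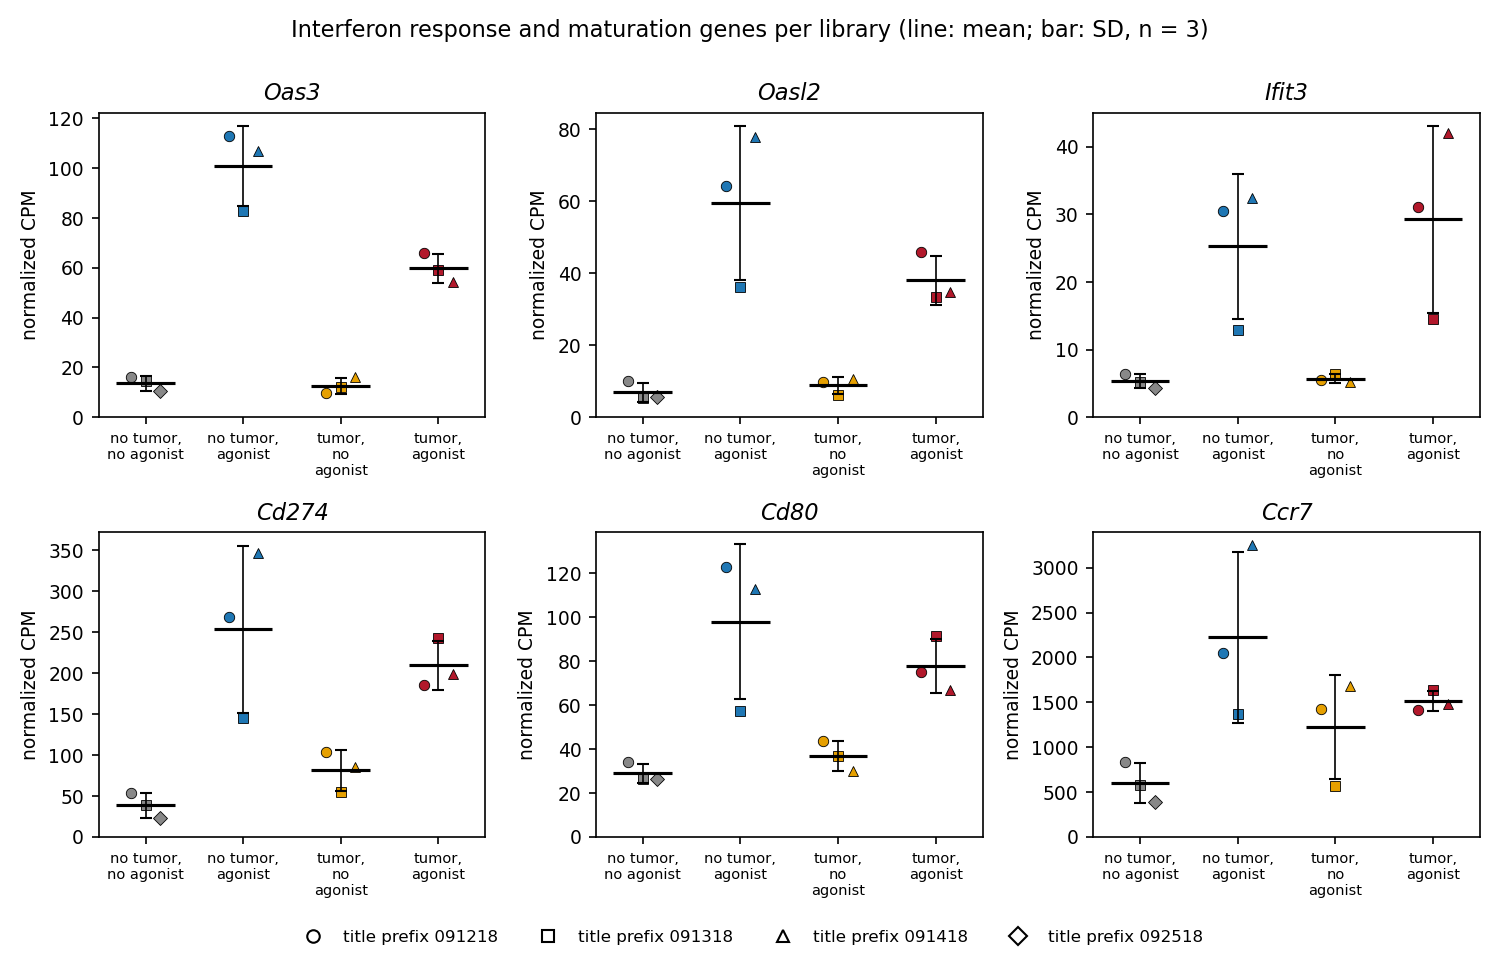
Normalized CPM of Oas3, Oasl2, Ifit3, Cd274, Cd80 and Ccr7 (y axis, linear) in the 12 libraries by group (x axis); the line is the group mean, the bar its SD (n = 3) and the marker shape the title prefix. Oas3 averaged 101 CPM in NoTumor-CD40 and 59.8 CPM in Tumor-CD40, against 13.6 and 12.7 CPM in the groups without the agonist.

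The comparison of Tumor-CD40 with Tumor-NoCD40 libraries asked what the agonist changed when a tumor was present. Interferon-stimulated genes rose here too, and B cell and immunoglobulin transcripts rose beside them. Ifi27l2a, an interferon-induced gene, rose from 22.3 ± 6.88 to 118 ± 9.21 CPM (n = 3 per group), a log2 fold change of 2.40 ± 0.28 (SE), and Rtp4, another, rose from 1.06 ± 0.503 to 14.6 ± 4.76 CPM, a log2 fold change of 3.79 ± 0.55. Fcer2a (ENSMUSG00000005540, chromosome 8, 3681737 to 3694175), which encodes the B cell surface protein CD23, rose from 8.69 ± 4.17 to 232 ± 131 CPM, a log2 fold change of 4.74 ± 0.60. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 0.00174 for Ifi27l2a, 0.00721 for Rtp4 and 0.0035 for Fcer2a. Of the 18095 genes tested, 124 passed, 116 higher and 8 lower. Of the 116, 24 were immunoglobulin genes and 32 were immunoglobulin genes or listed markers of B or plasma cells. The other 92 of the 124 were neither, though further genes of B cells can be among them.

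Of the 40 type I interferon genes, 12 rose with a tumor and 28 rose when adjusted over the list alone. The median log2 fold change was 1.41, and 39 of the 40 were above 0. Ifit3 (2.36 ± 0.41 SE) and Oas1a (2.29 ± 0.29) were among them, 2 members of gene families with similar copies. Of 30 interferon gamma genes, 3 rose and 10 rose when adjusted over the list alone, with a median of 0.49; all 3 encode GTPases induced by interferon: Irgm1 (1.20 ± 0.22), Tgtp2 (1.18 ± 0.23) and Igtp (0.96 ± 0.17). Of 18 coinhibitory genes none passed over all genes and 4 were higher when adjusted over the list alone, with a median of 0.38. The camera adjusted p with the preset correlation was 2.11e-57, 5.15e-12 and 0.000349 for these 3 lists, and the adjusted p with an estimated correlation was 0.00658, 0.0316 and 0.0312. None of the 32 mature dendritic cell genes passed, and their median was -0.26. Cd80 was at 1.08 ± 0.26 and Cd274 at 1.36 ± 0.33, neither past the threshold (edgeR adjusted p = 0.0873 and 0.0925), and Ccr7 was at 0.30 ± 0.38. Of 24 cholesterol biosynthesis genes none passed over all genes, but 12 were lower when adjusted over the list alone, with a median of -0.59 (camera adjusted p = 1.12e-11 with the preset correlation and 0.178 with an estimated correlation). The lower genes included Eno3, an enolase of glycolysis, from 286 ± 133 to 82.5 ± 19.5 CPM (-1.80 ± 0.37), the collagen-binding integrin gene Itga1 (-1.55 ± 0.28) and Dclre1c, which encodes the DNA repair nuclease Artemis (-1.32 ± 0.26).

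Of the 16 measured B cell markers, 9 rose with the agonist in the presence of a tumor and 14 rose when adjusted over the list alone, with a median log2 fold change of 3.10. Cr2, a complement receptor, rose from 5.51 ± 1.92 to 90.7 ± 81 CPM (4.05 ± 0.64 SE), and Ms4a1, which encodes CD20, rose from 13.9 ± 6.69 to 211 ± 132 CPM (3.93 ± 0.54). The camera adjusted p was 3.11e-39 with the preset correlation and 0.0312 with an estimated correlation. Of 9 plasma cell markers, 1 rose (Ighg2b, 3.63 ± 0.56) and 4 rose when adjusted over the list alone, with a median of 1.31 (camera adjusted p = 0.000142 with the preset correlation and 0.178 with an estimated correlation). Several immunoglobulin variable genes also passed, Igkv17-121 with the smallest adjusted p of the comparison (0.000202, edgeR), from 0.254 ± 0.0473 to 6.13 ± 1.67 CPM; these genes resemble each other, and their low values without the agonist leave the size of the change uncertain. Of 26 uptake and cross-presentation genes, 4 rose: Cybb, a subunit of the phagocyte oxidase (3.18 ± 0.51), the kinase Syk (1.41 ± 0.25), the GTPase Rac2 (1.14 ± 0.23) and the receptor Axl (1.03 ± 0.21). Cybb, Syk and Rac2 are also expressed in B cells, the list's median was 0.00, and its camera adjusted p was 0.0182 with the preset correlation and 0.22 with an estimated correlation. Ly6c2 of the monocyte list (2.72 ± 0.30), Siglec1 of the macrophage list (2.30 ± 0.47) and Kdr of the endothelial list (2.71 ± 0.52) rose as well, and Chil3 of the monocyte list stood at 0.649, 1.73 and 23.5 CPM in Tumor-CD40 libraries 1, 2 and 3. The Langerhans cell list had a median of -1.08 (camera adjusted p = 0.00508 with the preset correlation and 0.0984 with an estimated correlation). The count of 124 was 26, 226 and 48 without Tumor-NoCD40 library 1, 2 and 3, and 45 without Tumor-CD40 library 3. With the title prefix as a term, 229 genes passed, 116 of them among the 124.

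**Figure D2:**
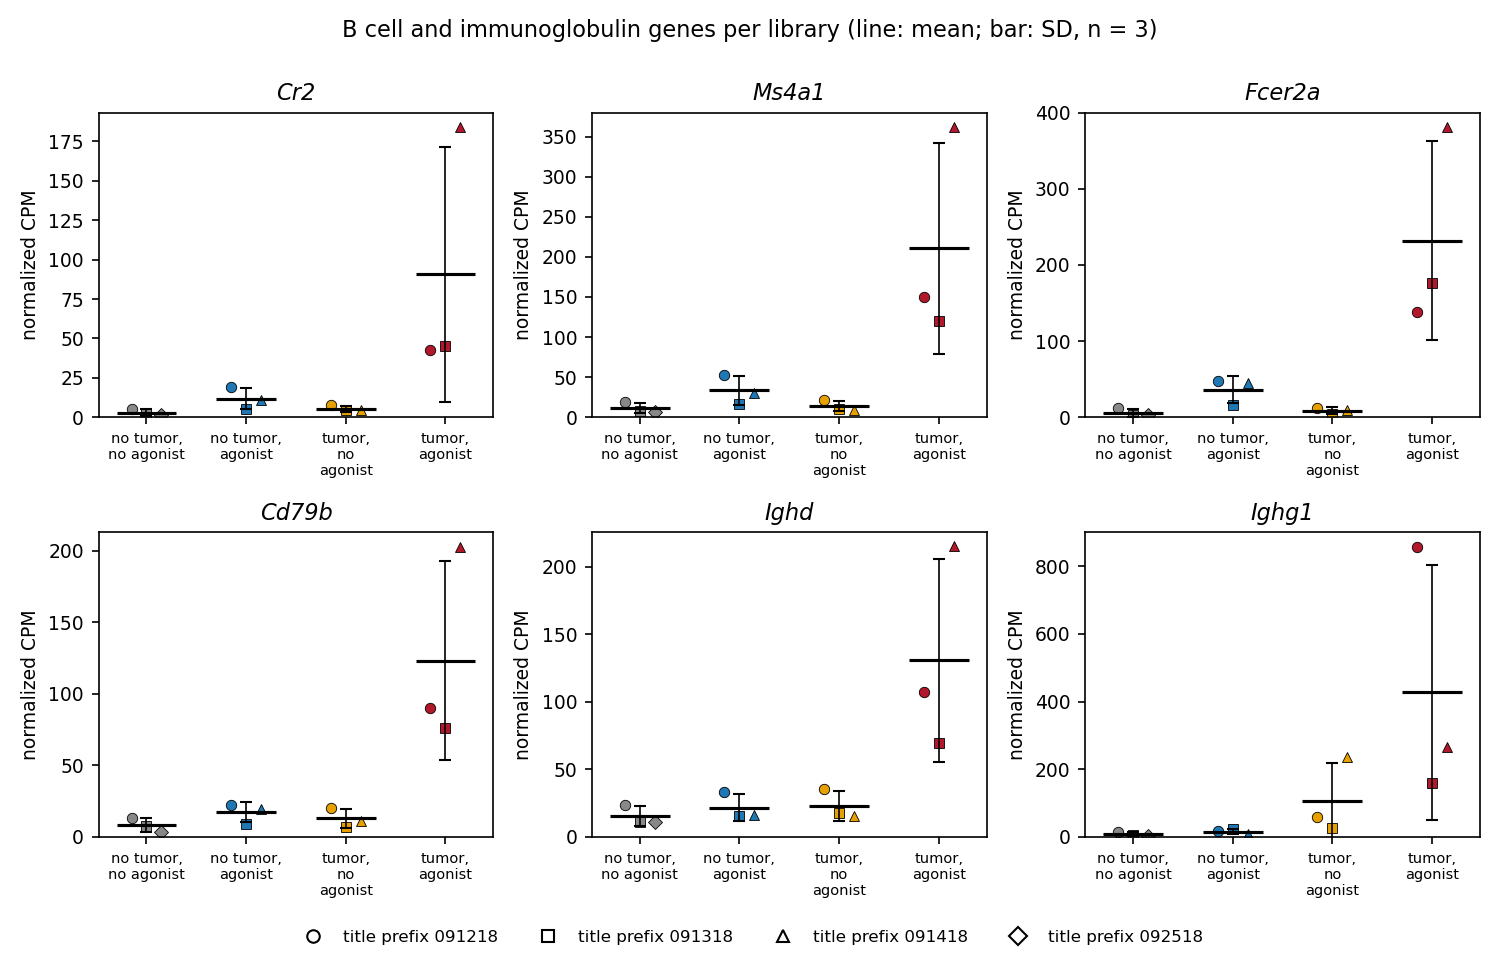
Normalized CPM (y axis, linear) of the B cell or immunoglobulin genes Cr2, Ms4a1, Fcer2a, Cd79b, Ighd and Ighg1 in the 12 libraries by group (x axis); the line is the group mean, the bar its SD (n = 3) and the marker shape the title prefix. Ms4a1 averaged 211 CPM in Tumor-CD40 and between 11.5 and 33.4 CPM in the other 3 groups.

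Whether the agonist acted alike with and without a tumor was asked in both directions, by the overlap of the changes and by the interaction. The 2 comparisons share no library. Across the 18095 genes, which are not independent replicates, the log2 fold changes had Pearson's r = 0.11 and Spearman's rho = 0.17, and r was 0.358 among genes with a mean of at least 5 CPM. Of the 246 genes higher without a tumor, 34 were also among the 116 higher with one, where independent lists of these sizes would share 1.58. The shared genes included the interferon-stimulated Oas3, Oasl2, Ifit3, Isg15, Rsad2, Xaf1 and Zbp1, and also Axl, Vdr, Upp1, Ly6c2 and Kdr. The sign was the same with a tumor for 235 of the 246, whose median log2 fold change was 1.59 without a tumor, where they were selected, and 0.57 with one. None of the 15 lower genes was among the 8 lower with a tumor, where independent lists of these sizes would share 0.00663, and the sign was the same in the other comparison for 11 of the 15 and for all 8.

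No gene passed the test of the interaction itself. edgeR's quasi-likelihood test gave 0 of 18095 genes, with 1773 at an unadjusted p under 0.05 where chance gives 905, and a smallest Benjamini-Hochberg adjusted p of 0.495. DESeq2 gave 18 genes and limma-trend on log2(TPM + 1) gave 2, or 7 without a filter, and limma-voom gave 0. Values with an adjusted p of 0.495 included Cd70 (-2.44 ± 0.65 SE), Ccr7 (-1.58 ± 0.54), Cd274 (-1.34 ± 0.47) and Fcrl1, a receptor of B cells (2.30 ± 0.50), where a negative value is a smaller agonist effect with a tumor. The mature dendritic cell list had a median of -1.32 in the interaction, with a camera adjusted p of 3.74e-20 with the preset correlation and an adjusted p = 0.316 with an estimated correlation. The type I interferon list had a median of 0.16 (camera adjusted p = 0.675). In simulated data with known changes, the interaction test recovered 50% of the genes changed 4-fold and 4% of those changed 2-fold, so differences of 2-fold or less were mostly not detectable with these libraries.

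**Figure D3:**
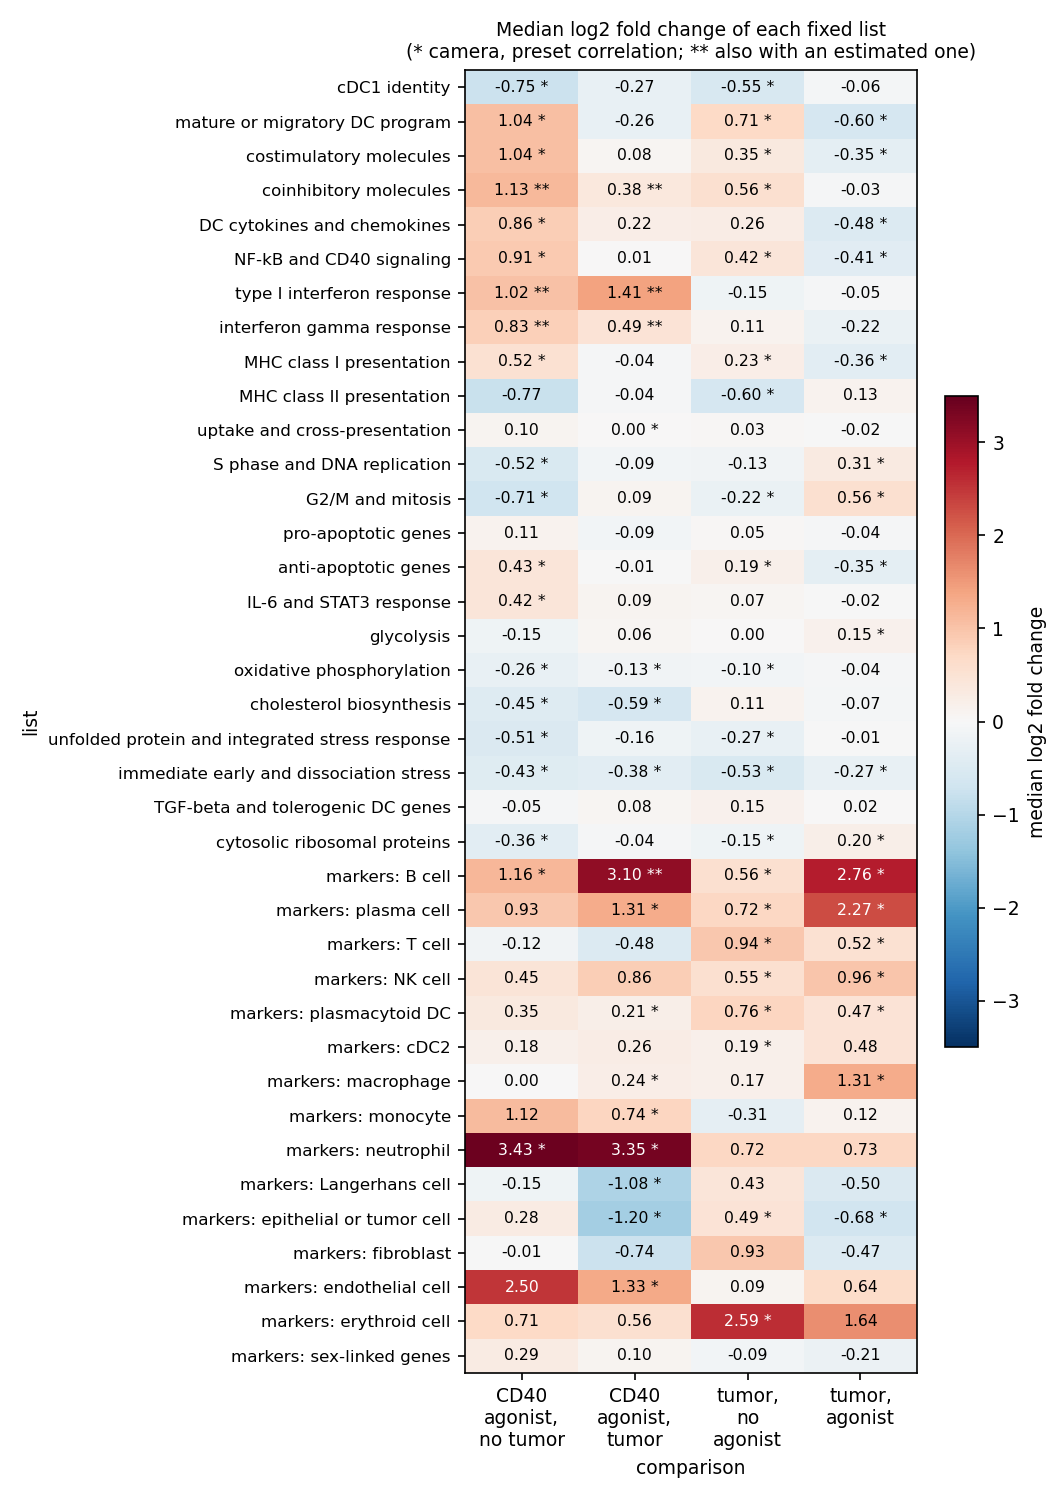
Median log2 fold change (color) of the 38 gene and marker lists (y axis) in the 4 pairwise comparisons (x axis). One asterisk marks a camera adjusted p under 0.05 with the preset correlation, a pair of asterisks one that also holds with an estimated correlation; the type I interferon list had medians of 1.02 and 1.41 with the agonist and the B cell list 3.10 with the agonist in the presence of a tumor.

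The comparison of Tumor-NoCD40 with NoTumor-NoCD40 libraries asked what the tumor alone changed in cDC1 of the inguinal node. Aldh1a2 (ENSMUSG00000013584, chromosome 9, 71215789 to 71296243), which encodes a retinaldehyde dehydrogenase that makes retinoic acid, averaged 4.67 ± 2.04 CPM without and 28.2 ± 8.68 CPM with a tumor (n = 3 per group), a log2 fold change of 2.58 ± 0.37 (SE). Pdcd1lg2 averaged 4.33 ± 1.75 and 15.4 ± 2.73 CPM (1.82 ± 0.32), and the actin-severing protein gene Scin 17.5 ± 7.37 and 68.7 ± 17.3 CPM (1.97 ± 0.44). None of these passed the test across all genes: by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.135 for Aldh1a2, 0.506 for Pdcd1lg2 and 0.775 for Scin. edgeR called 0 of 18095 genes, with 1053 at an unadjusted p under 0.05 where chance gives 905. DESeq2 called 29, limma-trend on log2(TPM + 1) with no filter 8, limma-trend with the filter and limma-voom 0, and edgeR called 2 without Tumor-NoCD40 library 3. Ctse, a cathepsin, averaged 51 ± 72.3 CPM without a tumor, where it was at 134 CPM in NoTumor-NoCD40 library 3 and at 10.1 and 8.4 CPM in the other libraries, against 6.82 ± 0.781 CPM with one (-2.89 ± 0.84). No list passed with an estimated correlation, the lowest adjusted p being 0.0606 for the coinhibitory list (median 0.56, 3 of 18 members higher when adjusted over the list alone, camera adjusted p = 9.26e-05 with the preset correlation). With the preset correlation the mature dendritic cell list had a median of 0.71 (camera adjusted p = 1.76e-16, and 0.42 with an estimated correlation) and the cDC1 identity list a median of -0.55 (6.52e-07, and 0.451 with an estimated correlation). The T cell marker list had a median of 0.94 (camera adjusted p = 8.13e-08, and 0.446 with an estimated correlation), and its summed expression was 774, 270 and 1350 CPM in Tumor-NoCD40 libraries 1, 2 and 3 against 326, 453 and 420 CPM in NoTumor-NoCD40. Plasma cell markers had a median of 0.72 (camera adjusted p = 6.11e-05, and 0.42 with an estimated correlation). They summed to 176, 74.5 and 419 CPM against 71.6, 48.9 and 48 CPM in the same libraries. Among other marker lists that passed with the preset correlation alone were B cell (median 0.56), epithelial or tumor cell (0.49) and erythroid (2.59). In simulated data the test of this comparison recovered 24% of the genes changed 2-fold and 76% of those changed 4-fold, so changes near 2-fold were mostly not detectable.

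The comparison of Tumor-CD40 with NoTumor-CD40 libraries asked what the tumor changed under the agonist. B cell, plasma cell and immunoglobulin transcripts were higher with a tumor, and so were some macrophage genes. Ighg1 (ENSMUSG00000076614, chromosome 12, 113325240 to 113330523), an immunoglobulin heavy chain constant gene, rose from 15.6 ± 7.1 to 427 ± 376 CPM (n = 3 per group), a log2 fold change of 4.77 ± 0.84 (SE). Cd79b, a signaling chain of the B cell receptor, rose from 17.2 ± 6.96 to 123 ± 69.5 CPM (2.85 ± 0.48), and C1qb, a complement component made by macrophages, rose from 1.17 ± 0.668 to 8.18 ± 0.871 CPM (2.81 ± 0.52). Prph, which encodes the intermediate filament peripherin, was the lower gene, from 48.3 ± 10.4 to 17.9 ± 1.78 CPM (-1.43 ± 0.23). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.0445 for Ighg1, 0.0425 for Cd79b, 0.0476 for C1qb and 0.0419 for Prph. Of 18095 genes 36 passed, 35 higher and 1 lower. Of the 36, 19 were immunoglobulin genes and 24 were immunoglobulin genes or B or plasma cell markers. Among the other 12, chosen by name after their values were seen, Bank1, Fcrl1, Pou2af1 and Ralgps2 are also known from B cells.

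Of the 16 B cell markers, 5 rose with a tumor under the agonist and 15 rose when adjusted over the list alone, with a median of 2.76, Cd22 (2.94 ± 0.53 SE) and Ighd (2.60 ± 0.46) among them. Of 9 plasma cell markers, 3 rose, with a median of 2.27, including Mzb1, a chaperone of antibody secretion (3.65 ± 0.66). Of 13 macrophage markers, 2 rose, C1qb and the scavenger receptor gene Marco (4.02 ± 0.76), with a median of 1.31. The camera adjusted p with the preset correlation was 3.24e-34, 1.74e-08 and 1.97e-06 for these 3 lists, and none passed with an estimated correlation (adjusted p = 0.113, 0.219 and 0.402). When adjusted over the list alone, 4 plasma cell and 5 macrophage markers were higher. The mature dendritic cell list had a median of -0.60 with 0 of 32 members past edgeR's threshold (camera adjusted p = 3.22e-08 with the preset correlation and 0.486 with an estimated correlation). The count of 36 was 7, 0 and 0 without NoTumor-CD40 library 1, 2 and 3, and 71 and 6 without Tumor-CD40 library 2 and 3, and it was 0 both with edgeR's legacy dispersion setting and among genes with a mean of at least 5 CPM. With the title prefix as a term, 83 genes passed, 35 of them among the 36.

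Libraries of the same group differed in the balance of cDC1 identity and mature dendritic cell genes. The summed expression of the identity list ran from 4740 to 20200 CPM and that of the mature list from 11000 to 51200 CPM over the 12 libraries. Their log2 values were inversely related, with Pearson's r = -0.84 (permutation p = 0.00088) and Spearman's rho = -0.76 (permutation p = 0.0056), both two-sided with 1e+05 draws. This relation was chosen from the 38 lists after the data were examined, so these p-values describe a chosen pair, and they treat the 12 libraries as interchangeable. Without the 2 libraries farthest from the median identity sum, Tumor-NoCD40 libraries 2 and 3, r was -0.78, and with each library taken relative to its group mean r was -0.87. The balance followed the title prefix in part: in all 4 groups the library of prefix 091318 had the highest identity sum, and in the 3 groups with a library of prefix 091418 that library had the lowest. Each prefix holds 4 libraries at most, too few for a value within one, and r was -0.96 for what remained after a fit with group and prefix. Relative to the prefix means r was -0.70, with an exact two-sided permutation p of 0.056 over the 3456 assignments within prefixes, so within prefixes the relation did not pass 0.05. Both lists are shares of the same total count.

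**Figure D4:**
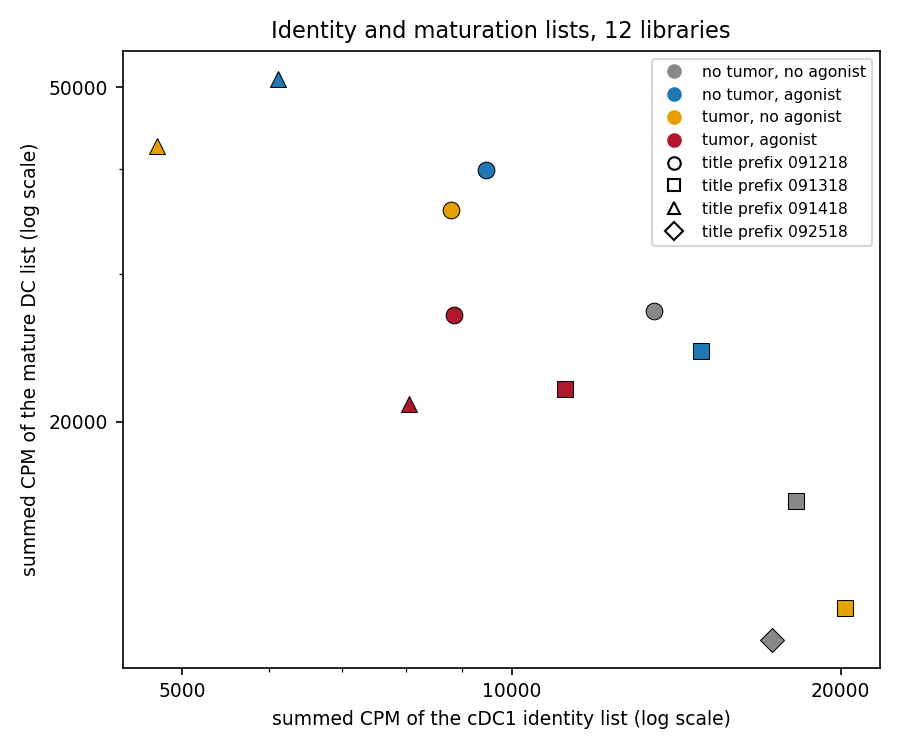
Summed CPM of the cDC1 identity list (x axis, log scale) and of the mature or migratory dendritic cell list (y axis, log scale), 1 point per library, colored by group, with the title prefix as marker shape. Tumor-NoCD40 library 3 has the lowest identity sum (4740 CPM) and Tumor-NoCD40 library 2 the highest (20200 CPM).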

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

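The tests of the B cell pattern, the prefix, within-prefix and single-library tests of the mature dendritic cell list and the covariate and prefix tests of the interferon list were chosen only after the results were seen; the permutation test of the mature list over all 12 libraries was not. What stood out is a difference between the CD40 agonist's effect with and without a tumor: in the interaction, 15 of the 38 lists passed camera with the preset correlation, 8 with a negative median (a lower log2 fold change with a tumor than without) and 7 with a positive one. None of the 15 passed with an estimated correlation, where their adjusted p ran from 0.168 to 0.705. By fry 1 of the 15 passed, the epithelial or tumor cell markers (adjusted p = 0.035, and 0.010 with the title prefix as a term), and the adjusted p of the others ran up to 0.651. The epithelial or tumor cell markers summed to means of only 16.1, 20.8, 26.1 and 14.7 CPM in NoTumor-NoCD40, NoTumor-CD40, Tumor-NoCD40 and Tumor-CD40. These are low values, and 7 of the 12 markers were measured. No single gene passed edgeR's test of the interaction (1773 at an unadjusted p under 0.05, 18 genes with DESeq2). Median log2 values below 0 were -1.32 for the mature or migratory dendritic cell program, -0.82 for NF-kB and CD40 signaling, -0.51 for MHC class I presentation, -1.05 for costimulatory molecules, -1.18 for epithelial or tumor cell markers, -0.54 for anti-apoptotic genes, -0.50 for coinhibitory molecules and -0.72 for cytokines and chemokines. Median values above 0 were 2.02 for B cell markers, 0.80 for G2/M and mitosis, 0.36 for cytosolic ribosomal proteins, 0.46 for S phase and DNA replication, 0.81 for macrophage markers, 0.72 for MHC class II presentation and 0.46 for cDC1 identity. With the title prefix as a term, the coinhibitory list (camera adjusted p = 0.0719) and the cytokine list (0.0632) no longer passed with the preset correlation. That fit in effect leaves NoTumor-NoCD40 library 3 out.

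The mature dendritic cell list, with its median of -1.32 in the interaction, is the first pattern weighed. Each SE beside a list median, here and for the next patterns, is that between libraries of the same contrast of the list's mean log2 CPM. No table argues against the technical explanations tried. A spread between libraries could account for it: assigning the 12 libraries to the groups at random gave an interaction of the list's mean as large as the real one (-1.22 ± 0.65 SE) with a permutation p of 0.10 (1e+05 draws), and all 3456 assignments within the title prefixes gave one as large as that with the prefix as a term (-0.83 ± 0.47) with an exact permutation p of 0.093. A fit with the prefix as a term in effect leaves NoTumor-NoCD40 library 3 out, and leaving it out without the term gave a median of -1.09 ± 0.67 SE. The title prefix (median -0.81 ± 0.47 SE with the prefix as a term) and a single library (-1.05 ± 0.67 without Tumor-NoCD40 library 3, the value nearest to 0, and down to -1.75 without NoTumor-NoCD40 library 1) stay open as well, because these errors reach past the point at which either explanation would be excluded. These errors between libraries replaced errors over the genes of the list after a first reading, under which both would have been excluded, and an effect of the tumor on maturation stays open, untested.

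The second pattern is the B cell and immunoglobulin signal of the Tumor-CD40 libraries, where the summed B cell markers were 2230, 1590 and 4030 CPM against 350 to 653 CPM in the other 9 libraries. A lower share of cDC1 would raise the markers of other cell types alike. Against Tumor-NoCD40, the T cell list argues against it as the whole cause, with a median of -0.48 (± 0.60 SE) beside 3.10 for the B cell list. The other marker lists also moved apart there, with medians of 3.35 (neutrophil), 1.33 (endothelial), 1.31 (plasma cell), 0.86 (NK cell), 0.74 (monocyte), 0.56 (erythroid), 0.26 (cDC2), 0.24 (macrophage), 0.21 (plasmacytoid dendritic cell), -0.74 (fibroblast), -1.08 (Langerhans cell) and -1.20 (epithelial or tumor cell). Against NoTumor-CD40, the T cell (0.52), NK cell (0.96) and macrophage (1.31) medians were positive too, beside 2.76 for the B cell list. Of the lists of other cell types, only fibroblast (-0.47), Langerhans cell (-0.50) and epithelial or tumor cell (-0.68) were negative in that comparison. The cDC1 identity list had medians of -0.27 against Tumor-NoCD40 and -0.06 against NoTumor-CD40 (camera adjusted p = 0.624 and 0.651 with the preset correlation). That list also varied inversely with the mature list, so it does not measure the share of cDC1 alone. A lower share of cDC1 thus stays open as a part of the rise. B cells or their RNA carried into these libraries cannot be told apart from a common rise of these genes within cDC1: 11 of the 16 B cell markers had the order of their sum over the 3 libraries, which either would give, since the sum is made of the same markers. The most abundant markers were at 847, 387 and 780 CPM (Igkc), 416, 376 and 833 CPM (Ighm) and 138, 177 and 381 CPM (Fcer2a) in libraries 1, 2 and 3, the labels give no sort gate that would remove such cells, and Fcrla, which was at 32.6 to 50.7 CPM in NoTumor-NoCD40, was the marker with no higher mean in Tumor-CD40 than in Tumor-NoCD40. Why these transcripts were higher in this group was not tested and stays open.

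The third pattern is the rise of the type I interferon list with the agonist, with medians of 1.02 without and 1.41 with a tumor. A change in the share of mature cDC1 as the whole cause is argued against by the medians with the mature list's mean as a covariate, 0.98 (± 0.22 SE) and 1.47 (± 0.17). Without a tumor, a difference between title prefixes is argued against in the same way, by a median of 0.98 (± 0.21) with the prefix as a term. That fit in effect leaves NoTumor-NoCD40 library 3 out, so it covers the other libraries only. With a tumor, each prefix that occurs held 1 library of both groups. A prefix term could therefore hardly move that median (1.40 ± 0.18), and this fit was no test. The balance itself leaves no room for a prefix difference common to both groups. Both groups with the agonist had an effect of this kind in libraries that were not shared, so a response of cDC1 to CD40 stimulation may account for it, as a hypothesis found and tested on the same data. Interferon made by other cells, and interferon-stimulated transcripts from other cells, were not tested.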

How the results depend on the processing

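Chosen after seeing the data were the covariates, the 8 libraries of prefixes 091218 and 091318, and the counts outside immunoglobulin genes and the listed B and plasma cell markers. The other alternatives were planned. Among the named genes past the threshold, fitted under all of these settings (94 of 114 with the covariates, 89 with a mean of at least 5 CPM), 1 turned direction: the Chil3 log2 fold change, CD40 agonist with tumor, became -1.92 with the B cell list as a covariate. The counts moved more. Genes changed by CD40 agonist without tumor (261) were 913 with DESeq2, 401 with no filter, 173 with only the 6 libraries compared, 48 with the prefix block, 31, 29 and 23 with limma-trend on log2(TPM + 1), on log2(TPM + 0.1) and on log2(TPM + 1) with no filter, 1255 with limma-voom and quality weights, 56 with the 8 libraries, 88 with the mature list and 74 with the B cell list as covariate, and 22 to 946 without single libraries. Genes changed by CD40 agonist with tumor (124) were 316 with DESeq2, 200 with no filter, 71 at a mean of at least 5 CPM, 25 with only the 6 libraries, 229 with the block, 29, 21 and 16 with the limma-trend settings in the same order, 61 with legacy = TRUE, 414 with the mature list and 0 with the B cell list as covariate, and 26 to 226 without single libraries; the B cell list is high in all 3 Tumor-CD40 libraries, so this covariate takes up the group difference itself. Genes changed by tumor without CD40 agonist (0 by edgeR, 1053 at an unadjusted p under 0.05) were 29 with DESeq2, 1 with no filter, 8 with limma-trend on log2(TPM + 1) and no filter, and 0 to 2 without single libraries. Genes changed by tumor with CD40 agonist (36) were 166 with DESeq2, 89 with no filter, 0 at a mean of at least 5 CPM, 3 with only the 6 libraries, 83 with the block, 12, 6 and 7 with the limma-trend settings, 1 with limma-voom, 0 with legacy = TRUE, 12 outside immunoglobulin genes and the listed B and plasma cell markers (further genes known from B cells are among these 12), and 0 to 71 without single libraries. Genes with a tumor by CD40 agonist interaction (0 by edgeR, 1773 at an unadjusted p under 0.05) were 18 with DESeq2, 2 with limma-trend on log2(TPM + 1) and 7 with that and no filter. Pearson's r between the CD40 effects (0.11) was 0.358 at a mean of at least 5 CPM and 0.211 on log2(TPM + 1). In the comparison of the tumor without CD40 agonist the MHC class I list changed direction with the prefix block (camera adjusted p = 0.509). The block in effect leaves NoTumor-NoCD40 library 3 out. Fewer genes tested, fewer libraries or fewer residual degrees of freedom are part of several of these settings; beyond that the cause was not tested. Of 90 list calls with the preset correlation 83 were lost with an estimated correlation and 77 with fry, and 10 with the block. Of 114 calls of named genes 1 was lost with RLE factors, 0 with DESeq2, 50 with legacy = TRUE, 36 with limma-voom, 43 with the block and 92 on log2(TPM + 1), and leaving out single libraries ended 383 of 684. With these depths and this spread, changes under 2-fold were mostly not detectable.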

Other observations

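No test in this part was chosen after its result was seen: the lists and the splits of the samples were planned. With the agonist in the absence of a tumor, the G2/M and mitosis list had a median log2 fold change of -0.71 with 0 of 35 members past edgeR's threshold and 2 lower when adjusted over the list alone (camera adjusted p = 7.76e-12 with the preset correlation and 0.425 with an estimated correlation), and the S phase list had a median of -0.52 (4.06e-07 and 0.425). Mki67, the proliferation marker, averaged 107 ± 23.2 CPM without and 65.2 ± 34.7 CPM with the agonist (n = 3 per group) and did not pass (edgeR adjusted p = 0.301). Cytosolic ribosomal proteins had a median of -0.36 in this comparison (camera adjusted p = 1.15e-12 with the preset correlation and 0.425 with an estimated correlation). MHC class I genes had a median of 0.52 with 0 of 23 past edgeR's threshold and 11 higher when adjusted over the list alone (1.09e-06 and 0.425), while MHC class II genes had a median of -0.77 (0.0607 with the preset correlation), and the class II protease gene Lgmn rose (1.94 ± 0.42 SE). Of 28 genes of the IL-6 and STAT3 list, 2 rose (Il4ra, 1.51 ± 0.31, and Bcl3, 1.20 ± 0.19) and 7 rose when adjusted over the list alone, with a fry adjusted p of 0.00165 and a camera adjusted p of 0.0559 with an estimated correlation. The apoptosis genes Bcl2l11, a killer of the BCL2 family (1.36 ± 0.23), and Serpinb9, the inhibitor of granzyme B (2.02 ± 0.33), both rose.

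Some lists stood out in single libraries. The summed neutrophil markers were 39.5 CPM in NoTumor-CD40 library 1 and 2.91 and 3.09 CPM in libraries 2 and 3, and 29.3, 4.83 and 33.7 CPM in Tumor-CD40 libraries 1, 2 and 3. The summed erythroid markers were 61.7 CPM in Tumor-NoCD40 library 3 and 78.3 CPM in Tumor-CD40 library 3. Plasma cell markers summed to 1160, 293 and 523 CPM in Tumor-CD40 libraries 1, 2 and 3, and Ighg1 was at 857, 159 and 265 CPM there. The Langerhans cell markers summed to 17.8, 9.7 and 15.3 CPM in the Tumor-CD40 libraries and to 111 ± 16 CPM (mean ± SD, n = 3) in NoTumor-NoCD40. They were at 30.4, 86.5 and 18.2 CPM in NoTumor-CD40 and at 64, 89.1 and 44.4 CPM in Tumor-NoCD40. Low sums of this list were thus not confined to a single library or to Tumor-CD40. The sex-linked genes had a median of 0.29 with the agonist without a tumor (camera adjusted p = 0.738), and summed to 550 CPM in NoTumor-NoCD40 library 3 and to between 203 and 380 CPM elsewhere. This list mixes Xist with genes of the Y chromosome, which differ between the sexes in opposite directions. Its median, test and sum therefore cannot show whether the sexes were balanced.

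Each pairwise count was set against the 10 splits of its 6 libraries into groups of 3, too few for a share under 0.05. The real split gave 261 genes for the CD40 agonist without tumor, with 1 as the highest of the other splits, and 124 genes with tumor, with 2 as the highest other. It gave 36 genes for the tumor with CD40 agonist, with 2 as the highest other. In these 3 comparisons the real split was the 1 split with as many genes. For the tumor without CD40 agonist the real split gave 0 genes by edgeR (1053 at an unadjusted p under 0.05, and 29 with DESeq2), so all 10 splits gave as many, and the split of NoTumor-NoCD40 library 1 with Tumor-NoCD40 libraries 1 and 3 gave 601. That split points to a structure of the samples: its 2 sides are those with mature list sums of 27100, 35700 and 42600 CPM and of 16100, 11000 and 12000 CPM. For the interaction, all 100 splits drawn gave as many genes as the real one, which gave 0 (1773 at an unadjusted p under 0.05), and the highest other gave 2034. With a real count of 0 every split gives as many, so this count decides nothing about chance, and that of 2034 points to a structure of the samples.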
